A study of Saccharomyces cerevisiae with 27 samples.

How the data were processed

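RNA of 27 yeast samples was measured on one-colour Affymetrix arrays, 3 for each of 9 groups, 3 of them controls at 28 °C and 6 of them heat times at 41 °C. The values deposited are linear intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes, and the version of MAS5 and its scaling target are not given in the sources used here. No deposited intensity lies below 20, where 3.69% to 5.30% of the probe sets of an array lie exactly. Detection calls were not used here. The labels call the replicates biological replicates, and per the labels' protocols a culture was sampled repeatedly, so that replicates of the same number within heat or within control were taken as 1 culture.

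The table holds 9335 probe sets, of which 60 are array controls. In the probe annotation, 6504 of them name 1 gene, 328 several and 2443 none, and all 6504 gene IDs matched the reference table of gene names. The 328 were left out, and the 2443 were used only for a separate test. For each of 315 genes with several probe sets the one with the highest mean was used, which left 5656 tested genes, 8 of them at the floor on every array. Near-identical gene copies share probe sets and are uncertain as single genes.

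The rule for scaling was set before the data were examined, like the comparisons, the gene lists, the named genes and the alternatives not marked as added. It kept the deposited scale unless the array medians differed by a ratio above 1.2. Over the tested genes they lay between 441.62 and 566.35, a ratio of 1.28, so the arrays were quantile normalized over the tested genes. Over all probe sets the ratio was 1.197, under the limit, so the choice was a close one that depended on the probe sets used. The log2 values were taken after adding 113.81, the 10th percentile of the values, which understates the folds of dim genes. Fits used limma 3.58.1 in R 4.3.3, with 1 mean per group over all 27 arrays and eBayes with a trend. Adjusted p values are Benjamini-Hochberg values within a comparison, with 0.05 as the threshold.

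There were 17 comparisons, namely each heat time against the control at 0 min, 120 and 240 min of heat against the control of the same time, the difference between these last effects, controls at 120 and 240 min against 0 min, successive heat times and 360 min against 10 min of heat. The 8 comparisons of heat with control share control arrays, so their changes are not independent. Gene lists, 37 in number with 1072 genes of which 989 were measured, were tested with camera at a preset correlation of 0.01, and adjusted over the 296 tests of those 8 comparisons or over the tests of the other comparisons. Of the ribosomal proteins 80 of 137 and of the histones 4 of 10 were measured.

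The genes named were the 20 of a list fixed in advance (HTA1 is not measured), the 5 largest rises and 5 largest falls per comparison of heat with control (3 each in the others) among genes past the threshold whose 3 arrays of 1 group all lay above those of the other and whose higher mean exceeded the median level, without that overlap condition for the difference of the heat effects, and up to 4 members past the threshold per list with the largest absolute fold. Genes outside the rule are marked in the text.

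The test was tried on simulated data with 200 changed genes among 5656. For 10 min against 0 min, 100 of 100 genes with a log2 change of 1 and 89 of 100 with 0.5 were called, with 5 false calls. For 240 min against the control of the same time, the numbers were 100, 92 and 12. A proteasome list that was moved was called in both, and of 36 other lists 0 were called. The simulated genes were drawn independently, so false list calls from correlated genes could not occur and the list test was not tried against them. The changed genes were few, as many up as down, and each gene had 1 spread in all groups. In the real data 3468 or more genes were called in each comparison of heat with control. The median SD of a group ran from 0.065 to 0.118. Normalization and false calls under such wide change and unequal spread were not tried.

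Alternatives changed the scaling, the offset, the filter on dim genes, the rule for several probe sets, the probe sets with other suffixes, the variance trend, the arrays in the fit, the replicate block, the culture as a block, the control and each array in turn. For the lists, an estimated correlation and fry were also tried. Added after seeing the control probe sets of the arrays were a term for the background level, a subtraction of that background, a fit without replicate 3 at 10 min and a fit of the genes with a mean above the median of all tested genes. A group of genes examined further in the difference of the heat effects is not reported here.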

Results

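Transcript levels were measured on 27 one-colour Affymetrix arrays, each carrying biotin-labelled cRNA made from 20 µg of total RNA of Saccharomyces cerevisiae X2180-1A, a laboratory strain known as a haploid of mating type a, neither of which the labels state. Cells grew in aerated 500 ml fermentor cultures on minimal medium with 2% glucose at 28 °C. At an OD600 of 0.50 the cultures to be stressed were brought to 41 °C within 5 min, and samples followed after 10, 30, 60, 120, 240 and 360 min. Control cultures stayed at 28 °C and were sampled at 0, 120 and 240 min, when their OD600 was 0.50, 0.88 and 1.5. Each of the 9 groups held 3 biological replicates. The comparisons asked how transcript levels changed with time after the shift to 41 °C.

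Mean signal per array lay between 746 and 914, and replicate arrays of 1 group correlated with r between 0.984 and 0.997 across the probe sets. Heat arrays differed from control arrays in their background and in other array measures. The 19 probe sets for non-yeast transcripts had a mean log2 signal of 6.05 to 6.35 on the 9 control arrays, of 5.56 to 6.21 on the 3 arrays at 10 min and of 5.15 to 5.71 on the 15 later heat arrays. The ratio of 3' to 5' probe sets of SRB4 was 2.27 ± 0.24 (SD, n = 3) in controls at 0 min, 3.20 ± 0.21 at 10 min, 4.17 ± 0.22 at 30 min and 5.10 ± 0.44 at 360 min, while that of ACT1 was 0.980 ± 0.013 in controls at 0 min and 1.06 ± 0.02 at 360 min. That of SPT15 was 2.26 ± 0.10 in controls at 0 min and 3.02 ± 0.65 at 10 min. The group means of ACT1 were 0.951 to 0.983 in controls and 1.05 to 1.11 from 30 min on. Ribosomal RNA probe sets had a mean log2 signal of 8.17 to 9.14 on the control arrays, of 6.98 to 7.48 on those at 60, 120 and 240 min and of 6.79 to 8.57 at 360 min. The bacterial spike-in controls had one of 9.01 to 9.43 on the control arrays and of 8.48 to 9.01 from 60 min on. The number of arrays limits the precision of every value here. Changes are given as log2 folds ± SE, each from 3 arrays against 3, or from 12 arrays in 4 groups for the difference of the heat effects.

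**Figure D1:**
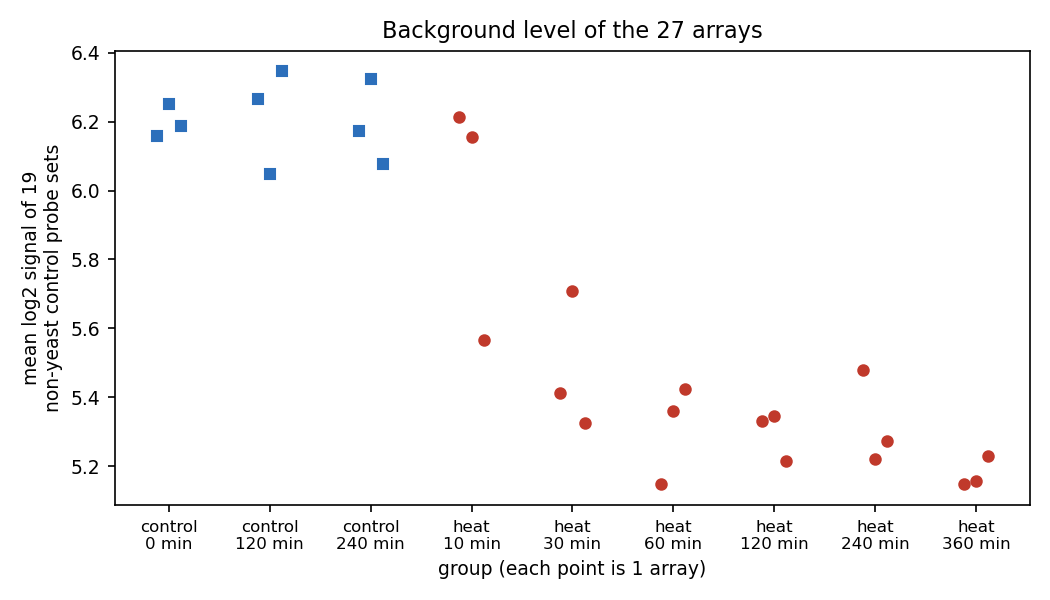
Mean log2 signal of 19 probe sets for non-yeast transcripts (vertical axis) on each of the 27 arrays by group (horizontal axis), with control arrays as blue squares and heat arrays as red circles. The 9 control arrays lie between 6.05 and 6.35, and the 15 arrays from 30 min on lie between 5.15 and 5.71.

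After 10 min at 41 °C, 4102 of 5656 tested genes differed from the cultures at 0 min, 1910 of them higher and 2192 lower, and 885 changed at least 2-fold (456 up, 429 down). The largest rise was that of HSP30 (YCR021C), a stress-induced plasma membrane protein, from a signal of 87.7 ± 18.9 (SD, n = 3) to 7752 ± 69.4, a log2 fold of 5.29 ± 0.09 (adjusted p = 1.86e-22). The non-yeast probe sets had mean signals of 71.5 to 76.3 on the control arrays at 0 min, so HSP30 lay near background there. Its log2 level with the offset was 7.42 to 7.78 on the control arrays of all times. The size of its fold, here and at later times, is therefore uncertain. HSP30 was followed by SSA4 (4.62 ± 0.12), a stress-induced Hsp70, by YNL194C (4.61 ± 0.16), a membrane protein of the Sur7 family, and by TMA10 (4.28 ± 0.15) and RGI1 (4.25 ± 0.11). The largest falls were those of the phosphate transporter PHO84 (-3.15 ± 0.16), the nucleolar proteins NOP1 (-3.04 ± 0.13), NIP7 (-2.89 ± 0.08) and RRP12 (-2.79 ± 0.14) and the branched-chain amino acid enzyme ILV5 (-2.75 ± 0.08). NOP1, the fibrillarin of the nucleolus, went from a signal of 3825 ± 69.9 to 379 ± 136. Of the genes at 2-fold, 48.8% were higher in the values as deposited, against 51.5% here.

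Several lists of stress genes rose at 10 min and others had no call. Of the cytosolic chaperones, 22 of the 24 measured members rose and 2 did not pass the test (adjusted p = 1.94e-12, adjusted p = 0.103 with an estimated correlation), among them the disaggregase HSP104 (2.95 ± 0.09), HSP82 (2.64 ± 0.08), the small heat shock proteins HSP42 (3.79 ± 0.10) and HSP26 (4.13 ± 0.09) and BTN2 (4.16 ± 0.12) and SSE2 (3.42 ± 0.09). All 28 measured targets of the general stress factors Msn2 and Msn4 rose (adjusted p = 3.62e-17, adjusted p = 0.0247 with an estimated correlation). Their median was 2.58, and they included the catalase CTT1 (3.93 ± 0.13), HSP12 (1.48 ± 0.10), SPI1 (4.12 ± 0.12) and SOL4 (4.01 ± 0.11). For trehalose metabolism, 9 of the 10 measured members rose and 1 did not pass the test (adjusted p = 6.16e-07, adjusted p = 0.0247 with an estimated correlation). The synthase subunits TPS1 (1.96 ± 0.06), TPS2 (2.68 ± 0.14) and TSL1 (2.33 ± 0.05) were examples. For glycogen metabolism, 10 of the 11 measured members rose and 1 did not pass the test (adjusted p = 6.93e-08, adjusted p = 0.0869 with an estimated correlation), led by GSY1 (3.75 ± 0.08), GPH1 (3.60 ± 0.11) and GAC1 (3.12 ± 0.15). For autophagy and vacuolar proteases, 21 of the 23 measured members rose, 1 fell and 1 did not pass the test (adjusted p = 1.71e-06, adjusted p = 0.0255 with an estimated correlation). ATG8 (2.23 ± 0.14) and APE1 (1.84 ± 0.13) were examples. The ubiquitin gene UBI4 (2.00 ± 0.07) and the proteasome regulator RPN4 (2.02 ± 0.10) rose, while the proteasome subunits had a median of 0.05 with 13 up and 6 down (adjusted p = 0.505). No call was made for the mitochondrial chaperones (7 up, 4 down, adjusted p = 0.111), oxidative stress (14 up, 6 down, adjusted p = 0.108), folding in the endoplasmic reticulum (6 up, 6 down, adjusted p = 0.668) and ubiquitin (12 up, 5 down, adjusted p = 0.068). Of the transcription factor genes, MSN4 (1.06 ± 0.08) rose, MSN2 (-0.46 ± 0.08) and YAP1 (-0.57 ± 0.09) fell, and HSF1 (0.16 ± 0.08) and HAC1 (-0.08 ± 0.10) did not pass the test. Without replicate 2 at 10 min HSF1 passed it, at 0.22.

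Of the lists named here as falling at 10 min, purine synthesis alone kept its call with an estimated correlation. Of the ribosome biogenesis genes, 87 of the 88 measured members fell and 1 did not pass the test, with a median of -1.39 (adjusted p = 5.99e-24, adjusted p = 0.0809 with an estimated correlation), CBF5 (-2.63 ± 0.14) being a further example. All 23 measured subunits of RNA polymerases I and III fell (adjusted p = 2.21e-08, adjusted p = 0.102 with an estimated correlation), such as RPC19 (-2.61 ± 0.10) and RPA12 (-2.58 ± 0.09). Of the ribosomal protein genes, 60 of the 80 measured members fell, 1 rose and 19 did not pass the test, with a median of -0.34 (adjusted p = 6.53e-06, adjusted p = 0.36 with an estimated correlation) and larger falls for RPL22B (-2.30 ± 0.09) and RPL13A (-1.63 ± 0.10). For translation factors, 23 of the 28 measured members fell and 5 did not pass the test (adjusted p = 6.53e-06, adjusted p = 0.169 with an estimated correlation), with NIP1 (-2.04 ± 0.09), a subunit of initiation factor eIF3. For methionine and sulfate assimilation, 24 of the 27 measured members fell and 3 did not pass the test (adjusted p = 2.53e-07, adjusted p = 0.147 with an estimated correlation). MET5 (-2.04 ± 0.10) and MET16 (-1.79 ± 0.11) were examples. For purine synthesis, 20 of the 21 measured members fell and 1 rose (adjusted p = 1.94e-06, adjusted p = 0.0365 with an estimated correlation). The IMP dehydrogenase IMD4 (-2.43 ± 0.11) and ADE4 (-2.13 ± 0.09) were examples. For ergosterol synthesis, 19 of the 25 measured members fell, 1 rose and 5 did not pass the test (adjusted p = 0.00252, adjusted p = 0.286 with an estimated correlation). For fatty acids and sphingolipids, 17 of the 24 measured members fell, 3 rose and 4 did not pass the test (adjusted p = 0.0414, adjusted p = 0.459 with an estimated correlation). The G1 cyclin CLN2 (-0.99 ± 0.09) also fell.

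Adjusted over the list alone, the counts of the lists named for 10 min were the same except for glycogen (11 rises), oxidative stress (15 rises) and the proteasome (10 rises, 4 falls). The 3' to 5' ratio of SRB4 was already raised at 10 min and moved with these groups. The array of replicate 3 at 10 min had the lower background of the later heat arrays. Without it, 829 genes changed at least 2-fold, 806 of them among the 885. SSA1 was the brightest tested gene on each of the 18 heat arrays, so the normalization fixes its log2 fold against 0 min at 0.98 ± 0.06 for every heat time. Its fold in the values as deposited was 1.07 ± 0.07 at 10 min and 0.95 ± 0.07 at 360 min. Near-identical copies, such as the SSA genes, HSP82 and HSC82, HXT6 and HXT7, and pairs of ribosomal protein or histone genes, share probe sequence and are uncertain as single genes.

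**Figure D2:**
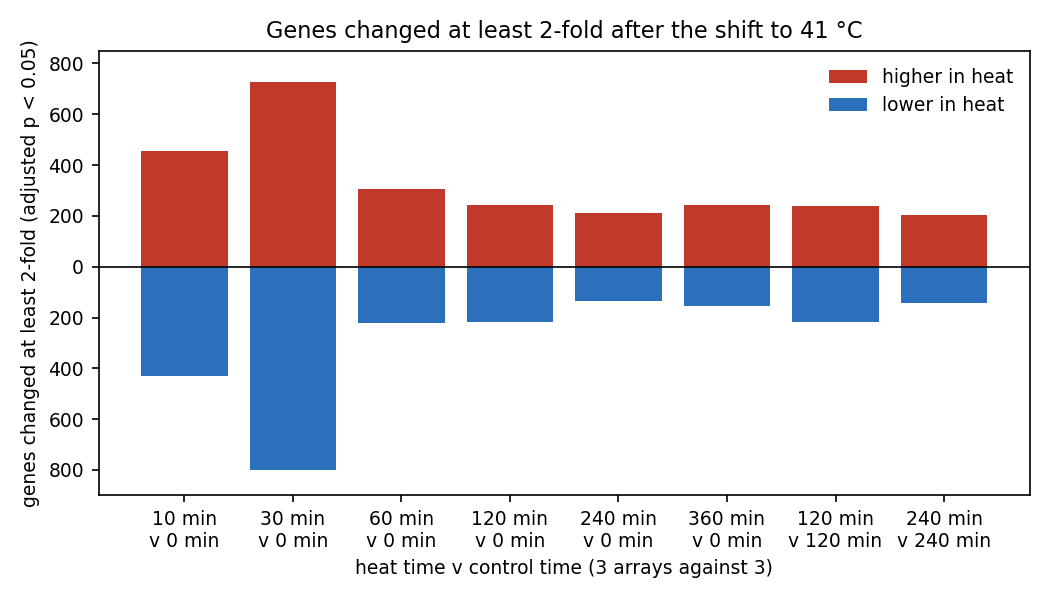
Number of genes (vertical axis) that changed at least 2-fold with an adjusted p under 0.05, above 0 for genes higher in heat and below 0 for genes lower in heat, for each heat time against a control time (horizontal axis, 3 arrays against 3). The counts are highest at 30 min, with 729 up and 801 down, and at 240 min against the control of the same time they are 203 and 143.

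The change was widest at 30 min, when 4577 genes differed from 0 min (2303 up, 2274 down) and 1530 changed at least 2-fold (729 up, 801 down). With the background level as a term, fewer genes were called at 30 min (3587) than at 10 min (3918). The counts at 2-fold kept their order, 1400 at 30 min and 829 at 10 min. These fits differ in precision, so the numbers called cannot be ranked. At 10 min the term only sets replicate 3 aside, and both counts are also those without that array. At 30 min the comparison carries the error of a term that rests on that array. HSP30 reached a signal of 12389 ± 245 (SD, n = 3) and a log2 fold of 5.96 ± 0.09 (adjusted p = 1.24e-23). This fold too is uncertain in size, as HSP30 lay near background in the controls. Next came YNL194C (5.07 ± 0.16) and SSA4 (4.89 ± 0.12), the mitochondrial protein FMP16 (4.85 ± 0.12) and FMP45 (4.67 ± 0.14), a membrane protein of the Sur7 family. The largest falls were now those of ribosomal protein genes, RPL13A (-3.75 ± 0.10), RPL7B (-3.51 ± 0.11), RPS1A (-3.44 ± 0.10) and RPL36B (-3.35 ± 0.16), together with NOP1 (-3.50 ± 0.13). RPL13A went from a signal of 6263 ± 619 to 360.2 ± 41.1. Of the called genes, 47.6% were higher in the values as deposited, against 50.3% here.

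At 30 min, 78 of the 80 measured members fell, 1 rose and 1 did not pass the test in the ribosomal protein list, with a median of -2.30 (adjusted p = 7.85e-25, adjusted p = 0.0346 with an estimated correlation). Ribosome biogenesis genes had a median of -1.81, and 87 of the 88 measured members fell and 1 did not pass the test (adjusted p = 6.71e-23, adjusted p = 0.0855 with an estimated correlation). All 18 tRNA synthetase genes fell (adjusted p = 3.37e-08, adjusted p = 0.111 with an estimated correlation), such as CDC60 (-2.80 ± 0.12) and DED81 (-2.69 ± 0.09), and so did all 23 subunits of RNA polymerases I and III (adjusted p = 8.16e-09, adjusted p = 0.0899 with an estimated correlation), such as RPA135 (-2.90 ± 0.08). Of the translation factors, 25 of the 28 measured members fell, 1 rose and 2 did not pass the test (adjusted p = 1.46e-07, adjusted p = 0.0971 with an estimated correlation). The elongation factor TEF4 (-2.76 ± 0.09) was an example. Amino acid synthesis fell broadly, and 52 of the 54 measured members fell, 1 rose and 1 did not pass the test (adjusted p = 9.07e-15, adjusted p = 0.0255 with an estimated correlation). ILV3 (-3.03 ± 0.10), HIS1 (-2.87 ± 0.09) and LYS4 (-2.68 ± 0.11) were examples. In purine synthesis 20 of the 21 measured members fell and 1 rose (adjusted p = 1.23e-08, adjusted p = 0.0247 with an estimated correlation). ADE17 (-2.95 ± 0.07), ADE6 (-2.90 ± 0.09) and GUA1 (-2.73 ± 0.08) were examples. In the methionine and sulfate list 25 of the 27 measured members fell and 2 did not pass the test (adjusted p = 6.06e-08, adjusted p = 0.12 with an estimated correlation). The sulfate transporter SUL1 (-3.30 ± 0.16) and SAM1 (-3.02 ± 0.09) were examples. For G1 and S phase genes 24 of the 36 measured members fell, 5 rose and 7 did not pass the test (adjusted p = 0.0164, adjusted p = 0.302 with an estimated correlation), with the ribonucleotide reductase RNR1 (-2.25 ± 0.11) and the cyclins CLN1 (-1.59 ± 0.09) and CLN2 (-1.37 ± 0.09).

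Among the stress groups at 30 min, all 28 Msn2 and Msn4 targets rose, with a median of 3.29 (adjusted p = 2.46e-14, adjusted p = 0.0272 with an estimated correlation) and with SOL4 (4.49 ± 0.11), ALD3 (4.41 ± 0.12), CTT1 (4.35 ± 0.13), HSP26 (4.45 ± 0.09) and HSP12 (1.71 ± 0.10). Of the cytosolic chaperones 23 of the 24 measured members rose and 1 did not pass the test (adjusted p = 1.34e-09, adjusted p = 0.169 with an estimated correlation). SSA3 (4.30 ± 0.19), HSP42 (3.88 ± 0.10), HSP104 (3.10 ± 0.09) and HSP82 (2.85 ± 0.08) were examples. In trehalose metabolism 9 of the 10 measured members rose and 1 fell (adjusted p = 0.000141, adjusted p = 0.0429 with an estimated correlation), with TPS1 (2.14 ± 0.06) and TPS2 (2.79 ± 0.14), and all 11 glycogen genes rose (adjusted p = 1.20e-05, adjusted p = 0.172 with an estimated correlation). GPH1 (4.09 ± 0.11) was an example. The proteasome list rose. Here 31 of the 32 measured members rose and 1 did not pass the test (adjusted p = 1.17e-05, adjusted p = 0.432 with an estimated correlation). RPN9 (1.40 ± 0.11) and RPN5 (1.28 ± 0.12) were examples, next to the regulator RPN4 (2.46 ± 0.10). In the ubiquitin list 17 of the 23 measured members rose, 2 fell and 4 did not pass the test (adjusted p = 0.00189, adjusted p = 0.169 with an estimated correlation). UBI4 (2.22 ± 0.07) was an example. Of the mitochondrial chaperones 8 of the 12 measured members rose, 1 fell and 3 did not pass the test (adjusted p = 0.0266, adjusted p = 0.446 with an estimated correlation). HSP78 (3.04 ± 0.09) and MDJ1 (2.80 ± 0.15) were examples. For folding in the endoplasmic reticulum 15 of the 20 measured members rose, 4 fell and 1 did not pass the test (adjusted p = 0.0342, adjusted p = 0.302 with an estimated correlation), with the oxidase ERO1 (2.38 ± 0.12), and for oxidative stress 17 of the 24 measured members rose and 7 fell (adjusted p = 0.0376, adjusted p = 0.279 with an estimated correlation). The peroxiredoxin TSA2 (3.10 ± 0.08) was an example. In the respiratory chain list 24 of the 40 measured members rose, 9 fell and 7 did not pass the test (adjusted p = 0.0348, adjusted p = 0.368 with an estimated correlation), led by the hypoxic and stress isoform of cytochrome c, CYC7 (4.51 ± 0.11). In autophagy 21 of the 23 measured members rose, 1 fell and 1 did not pass the test (adjusted p = 1.24e-06, adjusted p = 0.0255 with an estimated correlation). ATG8 (3.11 ± 0.14) was an example. The factor genes HSF1 (0.59 ± 0.08), MSN4 (0.77 ± 0.08), MSN2 (0.23 ± 0.08), YAP1 (0.51 ± 0.09) and HAC1 (0.29 ± 0.10) rose. Scaling decided 2 of these calls, as MSN2 (0.16) and HAC1 (0.07) were not called in the values as deposited. With all probe sets of a gene averaged HAC1 (0.04) was not called either. Both calls lie near the threshold, and they ended with similar folds when 1 array was left out, MSN2 at 0.18 without replicate 3 at 30 min and HAC1 at 0.26 without replicate 3 of the control. With the background level as a term YAP1 (0.19), MSN2 (0.10) and HAC1 (0.36) were not called. That term widens the SE, and HAC1 lost its call with a larger fold than the 0.29 of the main fit. A call lost this way does not by itself tie a change to background.

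Several lists had no call at 30 min, and their members moved both ways. Glycolysis had a median of -0.07 (adjusted p = 0.893) although the stress isoform of glyceraldehyde-3-phosphate dehydrogenase, TDH1 (3.29 ± 0.11), rose, and the tricarboxylic acid cycle had a median of 0.01 (adjusted p = 0.932). The mitochondrial ribosome (median 0.03, adjusted p = 0.893), the cell wall list (median 0.49, adjusted p = 0.173), glucose-repressed genes (median 0.23, adjusted p = 0.0647), phosphate starvation genes (median -0.36, adjusted p = 0.54) and genes induced by pheromone (median 0.12, adjusted p = 0.53) were not called either. Median, mean and test did not share 1 sign for glycolysis, the tricarboxylic acid cycle, the mitochondrial ribosome and the phosphate genes, a difference seen only in lists without a call. Within the cell wall list the kinase SLT2 (2.43 ± 0.13) rose and the glucanase SCW10 (-2.61 ± 0.16) fell. Meiosis and sporulation genes, which growing cells do not use, had a median of 0.16, and 23 of the 41 measured members rose, 6 fell and 12 did not pass the test (adjusted p = 0.0119, adjusted p = 0.399 with an estimated correlation). The 14 reference genes had a median of -0.05 (adjusted p = 0.893), with ACT1 (0.11 ± 0.05) not passing the test and CDC28 (1.35 ± 0.09) rising. Without replicate 2 of the control ACT1 passed, at 0.15. Adjusted over the list alone, the counts named for 30 min were the same except for the meiosis list (22 rises). The 3' to 5' ratio of SRB4, raised from 10 min on, and the lower background, from 30 min on, moved with all of these groups.

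**Figure D3:**
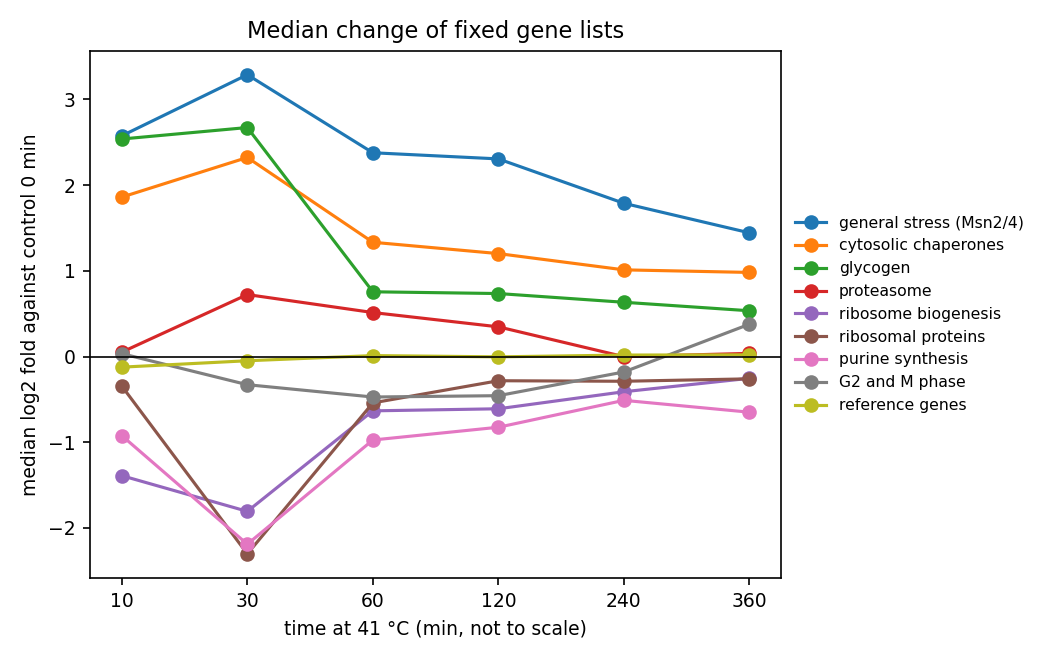
Median log2 fold against the control at 0 min (vertical axis) of 9 gene lists at 6 times at 41 °C (horizontal axis, in min, not to scale). General stress genes have the highest median at each time, 3.29 at 30 min and 1.44 at 360 min, and ribosomal protein genes go from -0.34 at 10 min to -2.30 at 30 min and -0.26 at 360 min.

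By 60 min the changes against 0 min were smaller, with 3920 genes called (1801 up, 2119 down) and 524 changed at least 2-fold (304 up, 220 down). HSP30 (5.05 ± 0.09) still led, followed by the sulfonate dioxygenase JLP1 (4.75 ± 0.18), HSP26 (4.37 ± 0.09), YCL048W-A (3.97 ± 0.11) and FMP16 (3.92 ± 0.12). The largest falls were those of SUL1 (-3.10 ± 0.16), TOS6 (-2.73 ± 0.24), the RNA helicase DBP2 (-2.64 ± 0.10), INA1 (-2.64 ± 0.13) and the adenine deaminase AAH1 (-2.57 ± 0.09). Ribosomal protein genes had come back to a median of -0.54 (adjusted p = 6.94e-12, adjusted p = 0.15 with an estimated correlation), with RPS0A (-1.46 ± 0.10) still low, and ribosome biogenesis genes to -0.63 (adjusted p = 2.46e-14, adjusted p = 0.196 with an estimated correlation). NSR1 (-1.85 ± 0.10) was an example. All 28 Msn2 and Msn4 targets were still raised (adjusted p = 4.80e-21, adjusted p = 0.0163 with an estimated correlation), with DDR2 (3.44 ± 0.08) and CTT1 (2.41 ± 0.13), and so were 23 of 24 cytosolic chaperones (adjusted p = 1.78e-13, adjusted p = 0.0899 with an estimated correlation). SSA4 (3.85 ± 0.12) and HSP82 (2.74 ± 0.08) were examples. In the proteasome list 26 of the 32 measured members rose and 6 did not pass the test (adjusted p = 1.85e-05, adjusted p = 0.435 with an estimated correlation). The G2 and M phase list fell. Here 18 of the 23 measured members fell, 2 rose and 3 did not pass the test (adjusted p = 0.00124, adjusted p = 0.294 with an estimated correlation). The septum chitin synthase CHS2 (-1.34 ± 0.08) was an example. In the cell wall list 19 of the 28 measured members rose, 7 fell and 2 did not pass the test (adjusted p = 0.00152, adjusted p = 0.36 with an estimated correlation). SLT2 (2.15 ± 0.13), PST1 (2.10 ± 0.08) and PIR3 (2.03 ± 0.11) were examples. In the values as deposited, 58.4% of the called genes were higher, against 45.9% here, and 69.5% against 58% of those at 2-fold.

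At 120 min the heat cultures could be set against controls of the same time, and 3899 genes differed (1886 up, 2013 down), 457 of them at least 2-fold (238 up, 219 down). The largest rises were HSP30 (5.09 ± 0.09), JLP1 (4.28 ± 0.18), HSP26 (4.20 ± 0.09) and SSA4 (3.91 ± 0.12) and the dehydrogenase isoform TDH1 (3.29 ± 0.11). That of HSP30 is uncertain in size, since its level in these controls lay near background. The largest falls were SUL1 (-3.02 ± 0.16), DBP2 (-2.80 ± 0.10), the daughter-cell glucanase DSE2 (-2.58 ± 0.18), the allantoate transporter DAL5 (-2.49 ± 0.09) and INA1 (-2.48 ± 0.13). Msn2 and Msn4 targets (28 of 28 up, adjusted p = 4.67e-21, adjusted p = 0.0163 with an estimated correlation) and cytosolic chaperones (23 of 24 up, adjusted p = 2.46e-14, adjusted p = 0.0809 with an estimated correlation) stayed raised, with HSP104 (2.74 ± 0.09), HSP42 (3.23 ± 0.10), HSP82 (2.75 ± 0.08), HSP12 (1.45 ± 0.10), CTT1 (1.99 ± 0.13), TPS1 (1.51 ± 0.06), TPS2 (1.60 ± 0.14) and UBI4 (1.56 ± 0.07). Proteins of the mitochondrial ribosome rose by a small amount, and 47 of the 68 measured members rose and 21 did not pass the test, with a median of 0.29 (adjusted p = 1.65e-05, adjusted p = 0.432 with an estimated correlation) and with MRPL24 (0.76 ± 0.10). In the proteasome list 26 of the 32 measured members rose and 6 did not pass the test (adjusted p = 0.000155, adjusted p = 0.492 with an estimated correlation). RPN9 (0.72 ± 0.11) was an example, next to the regulator RPN4 (1.80 ± 0.10). The measured histone genes fell, and 3 of the 4 measured members fell and 1 did not pass the test (adjusted p = 0.0268, adjusted p = 0.11 with an estimated correlation), namely HTZ1 (-1.32 ± 0.09), HTB2 (-1.24 ± 0.10) and HHO1 (-0.60 ± 0.10). In the G2 and M phase list 16 of the 23 measured members fell, 1 rose and 6 did not pass the test (adjusted p = 0.00177, adjusted p = 0.302 with an estimated correlation). CHS2 (-1.33 ± 0.08) and HOF1 (-0.78 ± 0.09) were examples. Purine synthesis (17 of 21 down, adjusted p = 3.28e-06, adjusted p = 0.0373 with an estimated correlation), with ADE17 (-1.82 ± 0.07), and amino acid synthesis (42 of 54 down, adjusted p = 1.91e-08, adjusted p = 0.0684 with an estimated correlation), with HIS1 (-1.58 ± 0.09), stayed low, the latter with 43 falls adjusted over the list alone. The G1 cyclin CLN2 (-0.49 ± 0.09) was still low, MSN4 (0.30 ± 0.08) was raised, MSN2 (-0.22 ± 0.08) and HAC1 (-0.62 ± 0.10) fell, and HSF1 (0.13 ± 0.08), YAP1 (0.10 ± 0.09) and ACT1 (0.01 ± 0.05) did not pass. In the values as deposited MSN2 (-0.11) did not pass and HSF1 (0.26) and YAP1 (0.27) did. MSN2 also did not pass without replicate 2 of the control (-0.13) or replicate 3 of the heat arrays (-0.19). With the background level as a term CLN2 (-0.39), RPN9 (0.46) and MSN2 (-0.35) were not called. That term widens the SE, and MSN2 lost its call with a larger fall than the -0.22 of the main fit.

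Against 0 min instead, 3896 genes differed at 120 min (1847 up, 2049 down), 463 of them at least 2-fold. The genes with the largest rises were the same ones, HSP30 (5.02 ± 0.09), JLP1 (4.30 ± 0.18), HSP26 (4.07 ± 0.09), SSA4 (3.80 ± 0.12) and TDH1 (3.44 ± 0.11), and the largest falls were SUL1 (-3.05 ± 0.16), DBP2 (-2.82 ± 0.10), DAL5 (-2.65 ± 0.09) and DSE2 (-2.51 ± 0.18) and the glycine decarboxylase subunit GCV2 (-2.46 ± 0.09). Scaling moved the balance at 120 min. In the values as deposited 65.1% of called genes were higher against 0 min (here 47.4%) and 62.1% against the control at 120 min (here 48.4%). Among genes at 2-fold the shares were 68.9% (here 52.7%) and 62.3% (here 52.1%). The median of all tested genes shifted in those values by 0.14 and 0.11 at 120 min, by 0.13 at 360 min against 0 min and by 0.15 between 360 and 10 min of heat, and the changes given here are relative to that shift.

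After 240 min, 3468 genes differed from the control of the same time (1597 up, 1871 down), and 346 did so at least 2-fold (203 up, 143 down). The largest rises were HSP30 (5.01 ± 0.09), HSP26 (4.18 ± 0.09) and SSA4 (3.52 ± 0.12), YRO2 (3.35 ± 0.11), a membrane protein related to HSP30, and JLP1 (3.34 ± 0.18). HSP30 was again near background in the controls, so the size of its rise is uncertain. The largest falls were SUL1 (-3.48 ± 0.16), the glycine decarboxylase subunits GCV2 (-2.85 ± 0.09) and GCV1 (-2.77 ± 0.11), PHO84 (-2.60 ± 0.16) and DAL5 (-2.41 ± 0.09). All 28 Msn2 and Msn4 targets were still higher, with a median of 1.70 (adjusted p = 6.41e-22, adjusted p = 0.0163 with an estimated correlation) and with DDR2 (2.72 ± 0.08), CTT1 (1.50 ± 0.13) and HSP12 (1.21 ± 0.10). Of the cytosolic chaperones 22 of the 24 measured members rose, 1 fell and 1 did not pass the test (adjusted p = 2.37e-14, adjusted p = 0.0809 with an estimated correlation). BTN2 (2.99 ± 0.12), HSP42 (2.85 ± 0.10), HSP82 (2.65 ± 0.08) and HSP104 (2.31 ± 0.09) and SSA1 (0.85 ± 0.06) were examples. In trehalose metabolism 9 of the 10 measured members rose and 1 fell (adjusted p = 5.96e-06, adjusted p = 0.0258 with an estimated correlation). TPS1 (1.16 ± 0.06) and TPS2 (1.41 ± 0.14) were examples. The ubiquitin list stayed raised. Here 13 of the 23 measured members rose, 2 fell and 8 did not pass the test (adjusted p = 0.00285, adjusted p = 0.184 with an estimated correlation), with UBI4 (1.40 ± 0.07), whereas the proteasome list had a median of -0.05 (adjusted p = 0.773) with RPN4 (1.61 ± 0.10) still high. In the cell wall list 15 of the 28 measured members rose, 3 fell and 10 did not pass the test (adjusted p = 0.000836, adjusted p = 0.329 with an estimated correlation). The glucan synthase GSC2 (1.88 ± 0.09), PIR3 (1.87 ± 0.11) and TIP1 (1.78 ± 0.08) were examples. Glycolysis was called up (adjusted p = 0.0359, adjusted p = 0.294 with an estimated correlation) with a median of 0.11 that was -0.01 in the values as deposited, and its largest members were TDH1 (3.13 ± 0.11) and PDC6 (2.18 ± 0.09). Ribosomal protein genes (53 of 80 down, adjusted p = 9.18e-06, adjusted p = 0.368 with an estimated correlation), ribosome biogenesis (62 of 88 down, adjusted p = 1.57e-07, adjusted p = 0.368 with an estimated correlation) and purine synthesis (16 of 21 down, adjusted p = 2.90e-06, adjusted p = 0.0373 with an estimated correlation), with ADE8 (-2.15 ± 0.16) and SHM2 (-2.08 ± 0.09), stayed below the control. Adjusted over the list alone, 54 ribosomal protein and 63 biogenesis genes fell. The cyclin CLN2 (-0.04 ± 0.09) no longer differed past the threshold, MSN4 (0.42 ± 0.08) was raised, HAC1 (-0.61 ± 0.10) was low, and HSF1 (0.13 ± 0.08), MSN2 (-0.07 ± 0.08), YAP1 (-0.17 ± 0.09) and ACT1 (0.09 ± 0.05) did not pass. With the background level as a term YAP1 fell (-0.49). Scaling moved this balance too, with 54.7% of the called genes higher in the values as deposited, against 46% here, and 63.7% against 58.7% of those at 2-fold.

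Against 0 min the heat cultures at 240 min differed in 3572 genes (1642 up, 1930 down), 348 at least 2-fold, led by HSP30 (4.89 ± 0.09), HSP26 (3.94 ± 0.09) and SSA4 (3.35 ± 0.12), the polyamine exporter TPO2 (3.34 ± 0.10) and YRO2 (3.33 ± 0.11) upward and by SUL1 (-3.56 ± 0.16), GCV2 (-2.88 ± 0.09), PHO84 (-2.61 ± 0.16), GCV1 (-2.61 ± 0.11) and DAL5 (-2.57 ± 0.09) downward. At 360 min, 3785 genes differed from 0 min (1795 up, 1990 down) and 397 did so at least 2-fold, with HSP30 (4.75 ± 0.09), HSP26 (3.82 ± 0.09), TPO2 (3.49 ± 0.10), YRO2 (3.40 ± 0.11) and SSA4 (3.15 ± 0.12) highest and SUL1 (-3.94 ± 0.16), PHO84 (-3.48 ± 0.16), GCV2 (-3.06 ± 0.09), GCV1 (-2.82 ± 0.11) and DAL5 (-2.48 ± 0.09) lowest. After 360 min the catalase CTT1 (1.08 ± 0.13) and HSP12 (1.18 ± 0.10), HSP104 (2.45 ± 0.09), HSP82 (2.72 ± 0.08) and HSP42 (2.83 ± 0.10) were still raised, as were 27 of 28 Msn2 and Msn4 targets (adjusted p = 3.62e-17, adjusted p = 0.0247 with an estimated correlation). The G2 and M phase list was now higher than at 0 min, and 13 of the 23 measured members rose, 2 fell and 8 did not pass the test (adjusted p = 0.00473, adjusted p = 0.354 with an estimated correlation). DBF2 (1.02 ± 0.07) and CLB1 (0.75 ± 0.08) were examples. In the G1 and S phase list 19 of the 36 measured members rose, 6 fell and 11 did not pass the test (adjusted p = 0.038, adjusted p = 0.368 with an estimated correlation). CLN2 (0.32 ± 0.09) was an example. In the cell wall list 18 of the 28 measured members rose, 2 fell and 8 did not pass the test (adjusted p = 5.48e-05, adjusted p = 0.254 with an estimated correlation). PIR3 (2.14 ± 0.11) and GSC2 (1.98 ± 0.09) were examples. In the values as deposited, 62.3% of the called genes were higher at 240 min against 0 min (here 46%) and 64.9% at 360 min (here 47.4%). Among genes at 2-fold, these shares were 76.1% (here 61.2%) and 76.9% (here 61%). The 10 min group is the only one with arrays of both background levels, so a term for that level rests on its replicate 3. The error of the term widens the SE of each comparison of a later heat time with a control. Calls are thus lost even without an effect of background. With that level as a term in the model, 2552 genes were called at 60 min, 2146 at 120 min, 1992 at 240 min and 1972 at 360 min against 0 min, and 2011 and 1931 at 120 and 240 min against controls of the same time. The counts at 2-fold moved less, to 493, 412, 317 and 339 against 0 min and to 384 and 312 against controls of the same time.

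**Figure D4:**
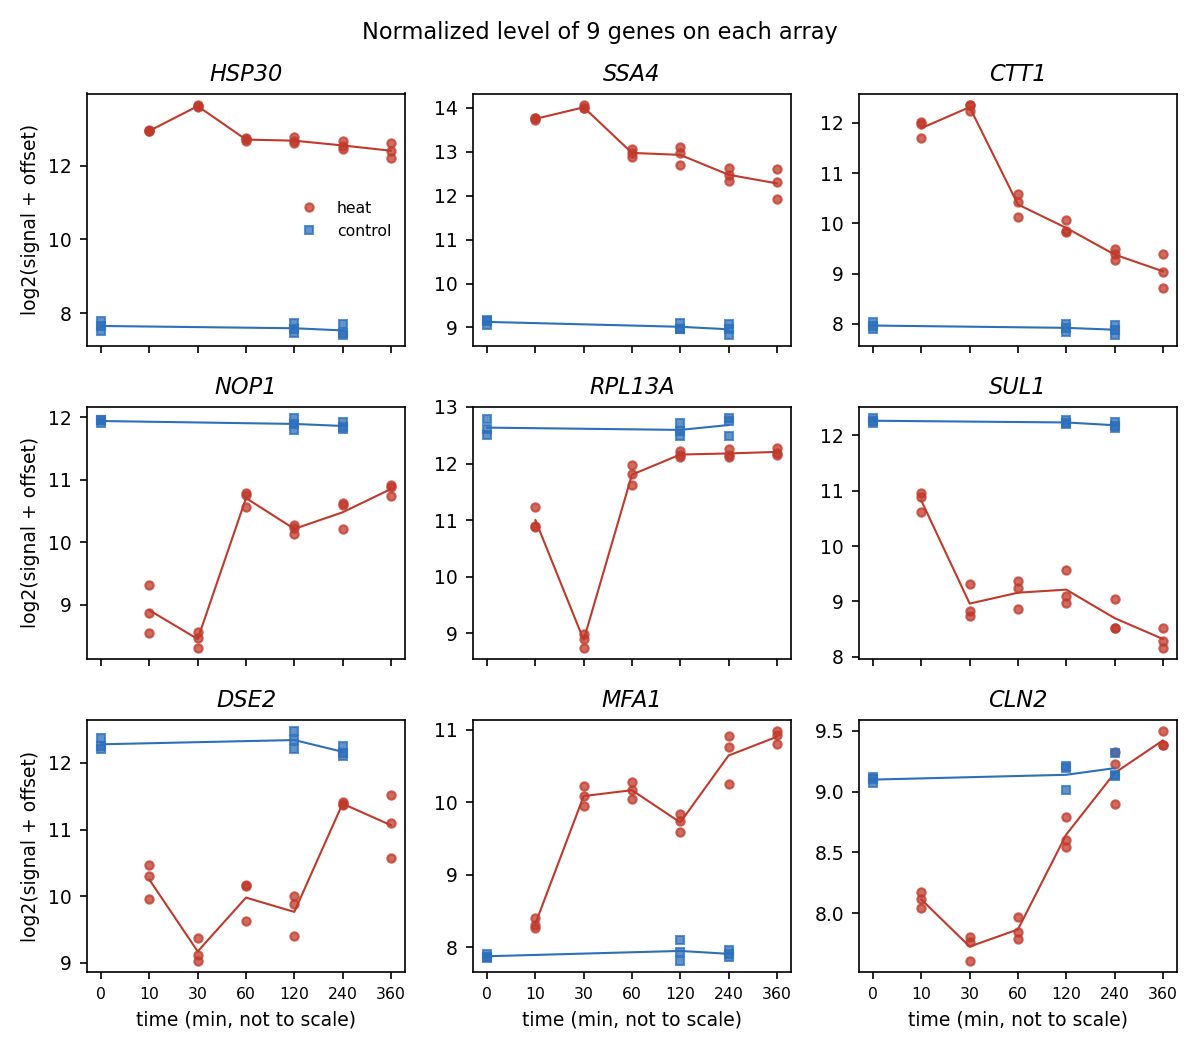
Normalized level of 9 genes on a log2 scale with the offset added to the signal (vertical axes) against time in min, not to scale (horizontal axes), each point 1 array, heat in red, control in blue, lines through the means of 3 arrays. HSP30 lies above all control arrays at each heat time, with log2 folds of 5.29 ± 0.09 at 10 min and 4.75 ± 0.09 at 360 min, and CLN2 goes from -1.37 ± 0.09 at 30 min to 0.32 ± 0.09 at 360 min. HSP30 is near background on the control arrays, so the size of its folds is uncertain.

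The heat effect itself, each time against its own control, differed between 240 and 120 min for 602 genes, 308 with a higher and 294 with a lower value at 240 min, and 31 of them by at least 2-fold. The largest increases were DSE2 (1.80 ± 0.26) and INA1 (1.68 ± 0.18) and the acid phosphatase PHO3 (1.68 ± 0.17), and the largest decreases were the amino acid transporter AGP3 (-1.10 ± 0.20), the glycine decarboxylase subunit GCV3 (-1.04 ± 0.18) and JLP1 (-0.94 ± 0.25). Among the genes fixed in advance, HSP104 (-0.43 ± 0.12) and TPS1 (-0.35 ± 0.09) decreased and CLN2 (0.45 ± 0.13) increased. These calls and that of JLP1 lie near the threshold, and leaving out 1 array could end them with folds of similar size. CLN2 was not called at 0.42 without replicate 1 or 2 of either control, at 0.40 and 0.43 without replicates 2 and 3 at 120 min of heat, and at 0.36 and 0.41 without replicates 1 and 3 at 240 min. HSP104 was not called at -0.35 without replicate 1 of the control at 120 min, -0.38 without replicate 3 of the control at 240 min, -0.38 without replicate 3 at 120 min of heat, and -0.42 and -0.40 without replicates 1 and 2 at 240 min. TPS1 was not called at -0.31 without replicate 3 at 120 min and -0.27 without replicate 2 at 240 min of heat. JLP1 was not called at -0.78 without replicate 2 at 120 min and -0.79 without replicate 1 at 240 min. CLN2 (0.37) was not called in the values as deposited either. For this difference the list test called 7 lists up and 9 down, against 0 with an estimated correlation and 17 with fry. Between controls, where few genes passed, it called 4 up and 7 down at 120 min and 4 up and 5 down at 240 min. With fry 0 lists were called between controls. The list calls given next rest on the preset correlation and are uncertain. The proteasome list decreased. Here 16 of the 32 measured members fell and 16 did not pass the test (adjusted p = 3.02e-13, adjusted p = 0.291 with an estimated correlation). RPN13 (-0.70 ± 0.15) was an example. For general stress 13 of the 28 measured members fell and 15 did not pass the test (adjusted p = 1.28e-08, adjusted p = 0.17 with an estimated correlation). GPX1 (-0.93 ± 0.12) and ALD3 (-0.71 ± 0.17) were examples. For the mitochondrial ribosome 19 of the 68 measured members fell and 49 did not pass the test (adjusted p = 1.25e-15, adjusted p = 0.265 with an estimated correlation). MRPS16 (-0.69 ± 0.16) was an example. The cell wall list increased. Here 12 of the 28 measured members rose and 16 did not pass the test (adjusted p = 7.78e-06, adjusted p = 0.291 with an estimated correlation). The glucanases SCW10 (1.11 ± 0.23) and SCW4 (0.75 ± 0.13) were examples. For ribosome biogenesis 13 of the 88 measured members rose and 75 did not pass the test (adjusted p = 1.64e-08, adjusted p = 0.441 with an estimated correlation). NSR1 (1.13 ± 0.14) was an example. For fatty acids and sphingolipids 5 of the 24 measured members rose and 19 did not pass the test (adjusted p = 0.00178, adjusted p = 0.385 with an estimated correlation). The desaturase OLE1 (1.02 ± 0.19) was an example. Of the histones 1 of the 4 measured members rose and 3 did not pass the test (adjusted p = 0.00773, adjusted p = 0.148 with an estimated correlation), the member past the test being HTB2 (1.34 ± 0.14). Adjusted over the list alone, the counts were 25 falls for the proteasome, 16 for general stress, 40 for the mitochondrial ribosome, and 15 rises for ribosome biogenesis and 3 for histones. The number of genes depended on single arrays, with 401 without replicate 1 of the control at 120 min, 399 and 400 without replicates 1 and 3 of the control at 240 min, 383 without replicate 3 at 120 min of heat and 399 without replicate 1 at 240 min of heat. In the values as deposited 28.8% of the called genes increased, against 51.2% here.

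Controls moved little among themselves. At 120 min against 0 min, 0 genes passed the limma test and 98 had an unadjusted p under 0.05. At 240 min, 4 genes passed and 220 had an unadjusted p under 0.05. Without any change a share of 0.05 of the 5656 tested genes would lie there, which is more than either number. The 2 falls were those of the sulfatase BDS1 (-0.61 ± 0.12) and YBR085C-A (-0.47 ± 0.08). Both rises, which lie outside the rule for named genes and were chosen after their values were seen, were those of the acyltransferase EEB1 (0.63 ± 0.09) and the small nucleolar RNA SNR34 (0.37 ± 0.07). Leaving out any 1 of the 6 arrays ended the calls of BDS1 (-0.67 to -0.52) and SNR34 (0.34 to 0.40). YBR085C-A was not called at -0.43 without replicate 2 at 0 min, and at -0.47 without replicate 1 or 2 at 240 min. Leaving out replicate 2 of the control at 120 min gave 4 genes at 120 min. At 240 min the 4 genes became 1 without replicate 2 of the control at 0 min, 1 without replicate 1 or replicate 2 of the control at 240 min and 2 without its replicate 3. They became 0 with the replicate block within cultures and 7 with the culture as a random block. The list test called 11 lists at 120 min, ribosome biogenesis with a median of -0.10 among them (adjusted p = 1.13e-21, adjusted p = 0.205 with an estimated correlation), and 9 at 240 min, and 0 of either with an estimated correlation or with fry.

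Between consecutive heat times, 3370 genes differed between 30 and 10 min (1898 up, 1472 down). Rises were led by SIP18 (2.96 ± 0.18), FIT2 (2.68 ± 0.15) and SRL3 (2.48 ± 0.09) and falls by RPS0A (-2.78 ± 0.10), RPL36B (-2.78 ± 0.16) and RPL13B (-2.76 ± 0.10). Over these 20 min, 77 of the 80 measured members fell, 1 rose and 2 did not pass the test among ribosomal protein genes (adjusted p = 6.59e-50, adjusted p = 0.0173 with an estimated correlation), and all 32 proteasome genes rose (adjusted p = 1.85e-08, adjusted p = 0.439 with an estimated correlation). From 30 to 60 min, 4049 genes changed (1823 up, 2226 down), with RPL7B (2.98 ± 0.11) and RPL13A (2.92 ± 0.10) and NEW1 (2.81 ± 0.11) rising most and YNL194C (-2.54 ± 0.16), the mitochondrial outer membrane protein OM45 (-2.34 ± 0.18) and EGO4 (-2.23 ± 0.09) falling most. Of the ribosomal protein genes 78 of the 80 measured members rose, 1 fell and 1 did not pass the test (adjusted p = 9.91e-36, adjusted p = 0.0357 with an estimated correlation). Of the ribosome biogenesis genes 87 of the 88 measured members rose and 1 did not pass the test (adjusted p = 5.75e-26, adjusted p = 0.17 with an estimated correlation). Of the amino acid genes 49 of the 54 measured members rose and 5 did not pass the test (adjusted p = 9.55e-16, adjusted p = 0.0357 with an estimated correlation). Glycogen genes fell back, all 11 of them (adjusted p = 6.28e-06, adjusted p = 0.265 with an estimated correlation). PIG2 (-2.08 ± 0.13) and GDB1 (-1.78 ± 0.08) were examples. Adjusted over the list alone, 78 ribosomal protein genes fell from 10 to 30 min and 50 amino acid genes rose from 30 to 60 min. In the values as deposited 61.6% of the genes called between 30 and 60 min were higher, against 45% here.

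Later steps involved fewer genes. From 60 to 120 min 1920 changed (1034 up, 886 down), with TOS6 (1.58 ± 0.24), the glucose transporter HXT1 (1.30 ± 0.17) and CSI2 (1.23 ± 0.12) rising most and RDN5-1 (-2.27 ± 0.35), HUG1 (-1.75 ± 0.12) and YBR090C (-1.65 ± 0.10) falling most. RDN5-1 is a ribosomal RNA without a poly(A) tail, so its level here is uncertain, as is that of SNR34. YBR090C was -0.18 and not called with plain probe sets only. In the mitochondrial ribosome list 61 of the 68 measured members rose and 7 did not pass the test (adjusted p = 1.13e-21, adjusted p = 0.17 with an estimated correlation). In the phosphate list 9 of the 16 measured members fell, 1 rose and 6 did not pass the test (adjusted p = 0.000121, adjusted p = 0.208 with an estimated correlation). PHO84 (-1.64 ± 0.16) was an example. From 120 to 240 min 1187 changed (568 up, 619 down), led by the vacuolar aminopeptidase APE1 (1.70 ± 0.13) and PHO3 (1.69 ± 0.12) and DSE2 (1.62 ± 0.18) upward and by AGP3 (-1.27 ± 0.14), BDS1 (-1.14 ± 0.12) and PHO84 (-1.05 ± 0.16) downward. Fits on the arrays of those groups alone called 1238 genes from 60 to 120 min and 550 from 120 to 240 min. From 240 to 360 min 458 changed (222 up, 236 down), with the acid phosphatase PHO5 (1.45 ± 0.10), the cytokinesis protein HOF1 (0.95 ± 0.09) and YNL058C (0.94 ± 0.12) rising most and the ammonium transporter MEP3 (-1.10 ± 0.14), JLP1 (-0.89 ± 0.18) and the dihydroxyacetone kinase DAK2 (-0.86 ± 0.12) falling most. Of the G2 and M phase genes 17 of the 23 measured members rose and 6 did not pass the test, with a median of 0.52 (adjusted p = 1.48e-24, adjusted p = 0.0118 with an estimated correlation) and with CLB1 (0.89 ± 0.08), BUD4 (0.86 ± 0.11) and SPO12 (0.85 ± 0.10). BUD4 was -0.073 and not called with plain probe sets only. JLP1 was not called in a fit on the arrays of those 2 groups alone, at -0.89. Adjusted over the list alone, 18 of these rose, as did 63 of the mitochondrial ribosome from 60 to 120 min. The count of 458 became 289 without replicate 1 and 246 without replicate 2 at 240 min, and 229 without replicate 3 at 360 min. The share of higher genes in the values as deposited was 67.1% for 60 to 120 min, 32.6% for 120 to 240 min and 64.1% for 240 to 360 min, against 53.9%, 47.9% and 48.5% here.

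From the first to the last heat time, 4105 genes differed (2016 up, 2089 down, or 49.1% up, and 64.8% up in the values as deposited). PHO3, the methionine enzyme MET2 and TPO2 rose most, by 3.40 ± 0.12, 2.97 ± 0.07 and 2.91 ± 0.10. The glycogen synthase GSY1 (-3.26 ± 0.08), YNL194C (-2.97 ± 0.16) and the nitrogen repressor DAL80 (-2.92 ± 0.15) fell most. In ribosome biogenesis 84 of the 88 measured members rose and 4 did not pass the test (adjusted p = 6.84e-23, adjusted p = 0.193 with an estimated correlation), with RRP12 (2.24 ± 0.14) and NIP7 (2.16 ± 0.08). In glycogen metabolism 10 of the 11 measured members fell and 1 did not pass the test (adjusted p = 4.89e-06, adjusted p = 0.265 with an estimated correlation). In general stress 21 of the 28 measured members fell, 1 rose and 6 did not pass the test (adjusted p = 1.72e-05, adjusted p = 0.291 with an estimated correlation). CTT1 (-2.85 ± 0.13) was an example. Of the 456 genes that were up at least 2-fold at 10 min against 0 min, 141 (30.9%) were so at 360 min against the control at 240 min, where independent lists would share 18.2 genes. Of the 429 that were down, 39 (9.09%) were so at 360 min, against 11.4 genes for independent lists. For 30 min, 178 of 729 rises (24.4%) and 75 of 801 falls (9.36%) were present at 360 min, where independent lists would share 29.1 and 21.2 genes. The control arrays at 0 min and at 240 min are different arrays, so these overlaps share no control array. By their replicate numbers the arrays still come from the same cultures, and all were normalized and fitted together. The counts for independent lists are therefore only a rough baseline.

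Over the 8 comparisons of heat with control, 154 of 296 list tests were called with the preset correlation, 35 with an estimated correlation and 235 by fry, which tests whether the genes of a list move on balance one way and does not set the list against other genes. With an estimated correlation the general stress, trehalose, purine and autophagy lists kept their call in all 8 comparisons.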

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

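The test on splits of all 12 arrays was set before the result was seen, and the splits of the control arrays alone were chosen only after it. By a test of the difference itself, the heat effect at 240 min differed from that at 120 min for 602 genes. The genes fixed by the rule for named genes were DSE2 (1.80 ± 0.26), INA1 (1.68 ± 0.18), PHO3 (1.68 ± 0.17) and CLN2 (0.45 ± 0.13) upward and AGP3 (-1.10 ± 0.20), GCV3 (-1.04 ± 0.18), JLP1 (-0.94 ± 0.25), HSP104 (-0.43 ± 0.12) and TPS1 (-0.35 ± 0.09) downward. Of 100 splits of the 12 arrays, 3 gave as many genes, the real one included, and the highest count of another split was 643. These splits do not settle whether chance can be excluded, since a split that parts the heat arrays removes their change from 120 to 240 min, and such splits gave at most 3 genes. With the heat arrays kept in their real groups, 4 of the 20 splits of the control arrays gave as many, the real one included, with 335 genes as the lowest count and 970 as the highest of the other splits.

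Probe sets with no gene in the annotation used here also changed. Of 2443, 1527 were called at 30 min against the control at 0 min, 113 rose at least 2-fold and 74 fell at least 2-fold. These shares are smaller than among the 5656 tested genes, of which 4577 were called, 729 rose and 801 fell at least 2-fold. For this test the arrays were normalized over all probe sets but the array controls, not over the tested genes. No biological explanation was tested for them.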

How the results depend on the processing

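Tests with the background level as a term, with background subtraction, on the brighter genes and without replicate 3 at 10 min were chosen only after the result was seen. No call of a list turned its direction under any alternative run. Of 4432 list values under alternatives, 221 lost the call and 121 gained one. Of 6695 values of named genes under alternatives, 6619 kept direction and side of the threshold, 65 lost the call, 10 gained one and 1 turned, BUD4 from 240 to 360 min, at -0.073 with plain probe sets only, where another probe set is read. Many named genes were chosen for large changes in the main fit, which by itself makes lost calls rare. Signal over background limits dim genes, whose folds depend on the offset.

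With an offset of 1 the counts at 2-fold became 1335 at 10 min, 893 at 60 min, 861 at 120 min, 669 at 240 min and 773 at 360 min against 0 min, and 852 and 617 at 120 and 240 min against controls of the same time. With an offset 4 times the main one they became 399, 877, 236, 213, 150 and 159 at the 6 heat times in order, and 219 and 152 against controls of the same time, because the offset itself shrinks folds. The brighter 2828 genes, fewer genes by construction, gave 2126 (531 at 2-fold) at 10 min, 2394 (1017) at 30 min, 2036, 2019, 1820 and 1919 at 60 to 360 min, 2022 and 1775 against controls of the same time, 397 for the difference of the heat effects, and 1902, 2084, 1079, 713 and 191 between successive heat times and 2002 between 360 and 10 min. A background term gave 2552, 2146, 1992 and 1972 at 60 to 360 min and 2011 and 1931 against controls of the same time. Only the 10 min group holds both background levels, so the term rests on replicate 3 there against replicates 1 and 2. Its error enters each of these comparisons and widens the SE. Calls are therefore lost even if background has no effect, and the counts cannot tell what background accounts for. At 2-fold the same fits gave 493, 412, 317 and 339, and 384 and 312. Fits on the arrays of the groups alone gave 1238 from 60 to 120 min and 550 from 120 to 240 min, with fewer arrays to estimate the spread. Of the list calls, 154 became 35 with an estimated correlation and 235 with fry.

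For controls at 120 min, where 0 genes passed in limma and 98 had an unadjusted p under 0.05, an offset 4 times the main one gave 1. For controls at 240 min the 4 genes became 7 with the values as deposited, 7 with that offset and 9 with background subtracted. The replicate block within cultures gave 0 and the culture as a random block 7, the consensus correlation of cultures being 0.0861. No other count moved by over 1.5 times under a block or pairing of replicates. Same-numbered heat arrays had a median correlation of deviations of 0.125 over 45 pairs, 24 of them over 0.1, against -0.04 for 90 other pairs, and same-numbered control arrays -0.09 over 9 pairs, so the numbers do not pair all arrays.

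Leaving out 1 array at a time gave 0 to 4 genes for controls at 120 min (4 without replicate 2 at 120 min), 1 to 3 for controls at 240 min (1 without replicate 2 at 0 min and 1 without replicate 1 or 2, 2 without replicate 3, at 240 min), 383 to 739 for the difference of the heat effects and 229 to 335 from 240 to 360 min. For the difference, the lowest came without replicate 3 at 120 min of heat, and 401, 399, 400 and 399 without replicate 1 of the control at 120 min, replicates 1 and 3 of the control at 240 min and replicate 1 at 240 min of heat. From 240 to 360 min, 289 and 246 came without replicates 1 and 2 at 240 min and 229 without replicate 3 at 360 min.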

Other observations

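Tests on the brighter genes, on 10 min arrays 1 and 2, on the batch of the arrays, on the values as deposited and on plain probe sets were chosen only after the result was seen, while saturation and the splits of the arrays were set before it. Genes used by a cells, those of the mating type the strain name stands for, rose at 30 min, where 6 of the 7 measured members rose and 1 did not pass the test (adjusted p = 0.035, adjusted p = 0.427 with an estimated correlation), with MFA1 (2.21 ± 0.12), BAR1 (1.26 ± 0.05), STE2 (0.88 ± 0.09) and MFA2 (0.83 ± 0.12). At 240 min against the control of the same time 5 of the 7 measured members rose and 2 did not pass the test (adjusted p = 0.00749, adjusted p = 0.323 with an estimated correlation), with MFA1 (2.74 ± 0.12) and AGA2 (0.70 ± 0.08). Genes used by alpha cells had no call at 30 min (median -0.35, adjusted p = 0.889), and of these MF(ALPHA)1 (-1.24 ± 0.18) fell and the receptor STE3 (0.77 ± 0.05) rose, with 1 up and 2 down in all. In controls at 0 min the signal was 121 ± 5.37 (SD, n = 3) for MFA1, 69.5 ± 14.7 for the a-cell receptor STE2, 39.8 ± 3.9 for the alpha-cell receptor STE3 and 1059 ± 122 for MF(ALPHA)1, and 28.6 ± 7.8 for GPA1, a gene of haploid cells, chosen after its values were seen. The non-yeast probe sets of those 3 arrays had mean signals of 71.5 to 76.3, so STE2, STE3 and GPA1 did not lie above background there and their folds against 0 min are uncertain. The alpha-cell gene MF(ALPHA)1 was thus brighter than the a-cell gene MFA1, which is not the pattern of the mating type the strain name stands for. The labels state neither mating type nor ploidy, and neither was checked here in another way.

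Hexose transporters moved apart. At 10 min 7 of the 13 measured members rose and 6 did not pass the test (adjusted p = 0.0229, adjusted p = 0.368 with an estimated correlation), with HXT5 (3.56 ± 0.10), HXT6 (1.86 ± 0.16), HXT7 (1.76 ± 0.10) and HXT4 (1.67 ± 0.15). At 30 min the stress-induced HXT5 (4.26 ± 0.10) was high while HXT1 (-2.45 ± 0.17) and HXT3 (-2.15 ± 0.11) were low, and the list had a median of 0.05 (adjusted p = 0.81). At 120 min HXT2 (-2.16 ± 0.11) was low against the control of the same time. Iron uptake genes rose from 10 to 30 min, where 21 of the 27 measured members rose, 1 fell and 5 did not pass the test (adjusted p = 0.000706, adjusted p = 0.441 with an estimated correlation), with FIT2 (2.68 ± 0.15) and TIS11 (1.34 ± 0.10). Against controls of the same time at 240 min, FIT2 (2.48 ± 0.15) and ARN1 (1.38 ± 0.17) were high, and the list had a median of 0.10 (adjusted p = 0.156).

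Most heat arrays had a lower background, with a median signal of non-yeast probe sets of 35.0 on 16 arrays and 65.0 on the other 11. At 240 min against the control of the same time, 346 genes changed at least 2-fold. Of these, 268 (77.5%) had a mean above the median of all tested genes, that is of 504 or more. This share cannot tell whether a loss of background caused the changes, since the offset keeps dim genes from reaching 2-fold. The mean also takes in the heat arrays, so a gene can pass it by rising. For the 268 genes, a drop from 65.0 to 35.0 is small beside such a mean. A loss of background as the cause is argued against at 10 min, where the arrays with the background of the controls gave 93.7% as many 2-fold changes. Other differences between the batches of arrays cannot be told apart from heat from 30 min on. For RNA quality this holds at 10 min too, by the 3' to 5' ratio of SRB4. It was 2.97 to 3.39 on the arrays at 10 min and 1.98 to 2.81 on the control arrays. The ratio of ACT1 at 10 min, 0.987 by mean, lay near that of the controls. With the batch as a term 72.8% of the 2-fold calls at 240 min stayed, but that term rests on 1 array at 10 min.

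Ribosomal protein genes fell less than ribosome biogenesis genes at 10 min, with medians 1.05 apart, and by more at 30 min (-0.50). The offset shrinks folds of dim genes more, and the median signal at 0 min was 700 for biogenesis and 7008 for ribosomal protein genes. The order at 30 min may therefore come from the offset, as the gap was not computed with another one. Saturation of bright probe sets is argued against by the dimmer ribosomal protein genes, which differed by 0.044 (bootstrap range -0.12 to 0.17) from the brighter at 10 min, 40 genes against 40. Scaling and shared probe sets are argued against by gaps of 1.04 in the values as deposited and 1.03 with plain probe sets over 52 genes. A later fall of ribosomal protein transcripts may be biological, a hypothesis found on the same arrays.

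For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. Every other split also mixes the arrays of both groups. Where many genes changed, their change then enters the spread and keeps the count of that split low. The low counts of other splits are therefore no measure of what chance gives. The real counts were 4102, 4577, 3920, 3896, 3572 and 3785 at the 6 heat times against 0 min and 885, 1530, 524, 463, 348 and 397 at 2-fold, with 0 in each as the highest other count by limma. They were 3899 (highest other 23) and 3468 (0) against controls of the same time, with 457 and 346 at 2-fold (0). Between controls they were 0 (4, and 10 of 10 splits gave as many) and 4 (0), and between successive heat times 3370 (722), 4049 (4), 1920 (11), 1187 (5) and 458 (2), and 4105 (0) between 360 and 10 min. In all comparisons but that of controls at 120 min, 1 of 10 splits gave as many. For those controls the real count of 0 made 10 of 10 certain. For the list calls 2 of 100 splits gave as many as 154, the real one included, the highest other being 158. A random split can thus reach that number of calls, although few did, and no single list was tested this way.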
